A study of Mus musculus with 12 samples.

How the data were processed

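Gene expression was measured by RNA sequencing in kidneys of 12 mice, 3 in each of 4 groups. Per the labels, total RNA was extracted with TRIzol, libraries were made with a VAHTS Universal V10 kit and sequenced on a DNBSEQ-T7, and every library carried the same batch number. The authors deposited 1 table of FPKM, fragment counts scaled by gene length and library depth, for all 12 libraries, with 1 value per gene symbol. The labels name the mm10 genome build, HTSeq and DESeq2 without versions or roles, and the aligner and gene annotation are not given in the sources used here. The study also made proteomic measurements, which were not analysed here.

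The table held 25553 genes and every column matched a sample. Of the symbols, 24328 were found in the RefSeq annotation of GRCm38, the assembly behind mm10, from which the positions of named genes were taken. FPKM totals ranged from 465148 to 494620 per library. Because FPKM values of a library are whole reads times a constant per gene, the whole reads could be recovered from the steps between values for 25548 genes, at a tolerance of 1e-06, and not for 5. Recovered totals ran from 33035307 to 35632033 reads per library. They differed by at most 0.049% from the relative depth read from genes under an FPKM of 0.3, and relative depth varied from 0.981 to 1.06. A gene seen in few libraries can be recovered as a whole fraction of its reads, so these totals are a check of depth and were used in 1 alternative only. All 66 pairs of the 12 libraries were checked for duplicates, and no pair shared an equal FPKM above 0 in any gene. On recovered reads the lowest chi-square per gene of a pair was 12.06, where copies of 1 library would give about 1 or less.

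Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend in the empirical Bayes step. Genes with FPKM of at least 1 in at least 3 of the 12 libraries were kept, which left 12357. A single fit of 4 group means to all 12 libraries gave every contrast, so that the groups shared 1 estimate of the spread. The contrasts were normoxic RIRI against normoxic sham, preconditioned RIRI against normoxic RIRI, preconditioned sham against normoxic sham, preconditioned RIRI against preconditioned sham, and the interaction, which is the injury effect in preconditioned mice minus that in normoxic mice. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05, and all adjusted p values of genes are from limma. Log2 fold changes are given with their standard error (SE) and FPKM with their SD, each over 3 mice per group. A change of at least 2-fold means a log2 fold change of at least 1 in size on the scale of FPKM + 1. Genes of low FPKM therefore need a larger change in FPKM to count.

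For the share of injury genes that moved back, genes were called for the mean injury effect, the average of both RIRI groups minus the average of both sham groups. The share is the percent of them in which preconditioned RIRI minus normoxic RIRI had the opposite sign. The contrasts behind the share are orthogonal, so that no library enters both in a way that makes a reversal by itself. An injury score was computed for each library from the genes raised or lowered at least 2-fold by the mean injury effect. It was the mean log2 value of the raised genes minus that of the lowered genes, without centring. Scores were compared with a two-sided exact permutation test.

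Before the data were examined, 32 gene lists of cell type markers and pathways were fixed. They were tested with camera of limma at a preset inter-gene correlation of 0.01, BH-adjusted over the 29 lists with at least 3 tested genes, and again with an estimated correlation. T and NK cells and B and plasma cells had 1 tested gene each and the adrenal gland list had 0, so these lists were tested only in the alternative without a filter. Members of each list were also counted after adjusting p over the list alone.

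The rule for named genes was fixed before the data were examined as well. It took the 6 called genes with the largest increase and the 6 with the largest decrease of each comparison, given a mean FPKM of at least 5 in the higher group and, outside the interaction, no overlap between the groups. Symbols of predicted genes, clones and pseudogenes were passed over. It further took 2 to 4 called members of each list described, those with the smallest adjusted p, and the genes of the study's title whatever their values. Il17a has no row in the table and was not analysed here. Genes named outside this rule are said to be so.

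The alternatives tried were a pseudocount of 0.1, no filter, a filter at FPKM 5, median-ratio rescaling, quantile normalization, a fit of only the groups compared, no mean-variance trend, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library in turn. Further alternatives, limma voom on the recovered reads and the proximal tubule list without its male-biased members between the sham groups, were added after the data had been seen. The lists were not run with voom, and the interaction cannot be fitted to only 2 groups.

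The tests were tried on simulated data. Of 100 simulated changes of log2 1, the fit called 96% in normoxic RIRI against normoxic sham and 88% in preconditioned sham against normoxic sham. For the interaction it called 84%. Between 3.1% and 7.6% of calls were false over the simulated comparisons. Apart from the added changes, each gene had the same mean and spread in every group. The pairwise comparisons therefore differ here by random draws alone. The real groups spread unequally, so these rates do not measure power or false calls in the real comparisons. With voom, 51% of changes of log2 1 and 100% of changes of log2 2 were called. These reads were drawn with a fixed dispersion for all genes and not with the real spread of each gene. The 51% can therefore not be set against the 96% of the fit. On the real data voom called 8851 genes in normoxic RIRI against normoxic sham, and the main fit 8859. Camera called 3 of 3 shifted lists and 0 of 21 unshifted ones, the share came out at 78.8% for a true 80%, and read recovery was exact for 100% of 2766 simulated genes. The fit and camera were tried on genes simulated as independent, while correlations estimated in the real lists were 0.022 to 0.863. The 0 of 21 therefore does not measure false list calls in the real data, where regrouped libraries gave up to 19 called lists. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.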

Results

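Kidneys were taken from mice that had bilateral clamping of the renal pedicles for 45 min and 12 h of reperfusion (renal ischemia-reperfusion injury, RIRI) or a sham operation. Before surgery, the mice either breathed room air (normoxic) or were preconditioned in a chamber at 8% oxygen, with sessions of 2 h, 4 h and 8 h on days 1, 2 and 3. Each of the 4 groups, normoxic sham, normoxic RIRI, preconditioned sham and preconditioned RIRI, had 3 mice. The sex of the mice is not given in the labels. Recovered depth was 33035307 to 35632033 reads per library, and 11301 to 11804 genes per library had an FPKM of at least 1. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.994 to 0.995 among normoxic sham, 0.992 to 0.995 among preconditioned sham, 0.984 to 0.989 among normoxic RIRI and 0.986 to 0.991 among preconditioned RIRI libraries. Between groups they were 0.856 to 0.882 for normoxic RIRI with normoxic sham, 0.929 to 0.955 for preconditioned RIRI with preconditioned sham, and 0.985 to 0.992 for the sham groups.

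The comparison of normoxic RIRI with normoxic sham asks what the injury did to the kidney without preconditioning. Injured kidneys gained genes of damaged tubules and of inflammation and lost genes of tubular transport and metabolism. The largest increases were of Lcn2, which encodes a siderophore-binding protein used as a kidney injury marker, from an FPKM of 2.72 ± 0.82 to 2328 ± 730 (SD, n = 3), and of the keratin gene Krt20, with log2 fold changes of 9.27 ± 0.27 (SE) and 9.21 ± 0.29. Plin2, a coat protein of lipid droplets, rose by 7.51 ± 0.51, Havcr1, the kidney injury molecule of proximal tubules, by 7.20 ± 0.55, Sprr2f, a small proline-rich protein, by 6.90 ± 0.32, and Fosl1, a transcription factor of the AP-1 family, by 6.43 ± 0.24. In the other direction, Gatm, which makes the precursor of creatine, changed by -5.00 ± 0.31, from an FPKM of 365 ± 4.20 to 10.7 ± 3.44. Acmsd, an enzyme of tryptophan breakdown, changed by -4.71 ± 0.39, G6pc, the catalytic unit of glucose-6-phosphatase, by -4.56 ± 0.21, Hsd3b2, a steroid dehydrogenase, by -4.51 ± 0.42, Hykk, a hydroxylysine kinase, by -4.23 ± 0.17, and the succinate receptor gene Sucnr1 by -4.12 ± 0.31. BH-adjusted p (limma) was at most 1.72e-06 for these 12 genes. On mm10, Lcn2 lies on chromosome 2 from 32384637 to 32387739, Krt20 on chromosome 11 from 99428385 to 99438153, and Havcr1 on chromosome 11 from 46739822 to 46779578. Of 12357 genes tested, 5143 were higher and 3716 lower, of which 1379 and 1196 changed at least 2-fold. The 3 values of each group did not overlap in 9184 genes (74.3%), where chance gives 10%.

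Camera called 10 lists as higher with injury at the preset correlation and none of them at an estimated one. All 24 tubular injury genes were higher, with a median log2 fold change of 4.27. They included Spp1 (4.60), which encodes osteopontin, and Tnfrsf12a (4.82), the TWEAK receptor. All 11 tested neutrophil genes were higher (median 2.13), among them Mmp9 (1.53) and Csf3r (1.66), the receptor of granulocyte colony-stimulating factor. All 22 tested IL-17 and NF-kB response genes were higher (median 2.45), among them Cebpb (2.67). Lcn2 belongs to these 3 lists and Fosl1 to the first and the last. Mmp9, S100a8 and S100a9 belong to both the neutrophil and the response lists, whose results are therefore partly those of the same genes. Of 19 acute phase and STAT3 genes, 16 were higher, including Socs3 (3.98), a feedback inhibitor of cytokine receptors, and Stat3 (2.29), and Cfb was lower (-0.95). Of 15 targets of the antioxidant factor NRF2, 13 were higher and 1 lower, with Srxn1 at 4.33. Of 13 apoptosis, necroptosis and pyroptosis genes 12 were higher, including the necroptosis genes Mlkl (2.68) and Ripk3 (1.70). Of 14 immediate early genes 10 were higher, with Atf3 at 3.59 and Myc at 4.15. Of 11 p53 targets 9 were higher, with the cell cycle inhibitor Cdkn1a at 4.75, and of 10 glucocorticoid targets 8 were higher and 1 lower, with the metallothionein genes Mt2 at 5.49 and Mt1 at 4.34. Of 19 IL-17 receptors and adaptors 12 were higher, with the receptor subunit gene Il17rc at 1.31.

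With the preset correlation, camera adjusted p was 3.53e-10 for tubular injury, 0.000522 for neutrophils, 9.75e-06 for IL-17 and NF-kB response genes, 0.00247 for acute phase and STAT3, 0.000824 for NRF2 targets, 0.00896 for cell death genes, 0.0045 for immediate early genes, and 0.0257 for p53 targets. It was 0.0284 for glucocorticoid targets and 0.0257 for IL-17 receptors and adaptors. With an estimated correlation none of them was called, with adjusted p = 0.313 for tubular injury, NRF2 targets, cell death genes and p53 targets, 0.486 for neutrophils, 0.441 for response genes, 0.535 for acute phase and STAT3 and for immediate early genes, 0.631 for glucocorticoid targets, and 0.373 for receptors and adaptors. The glucocorticoid call was also lost without normoxic RIRI replicate 2 (adjusted p = 0.0657).

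The 6 lists called as lower with injury, at the preset correlation only, were of the tubule segments and of mitochondrial metabolism. All 24 proximal tubule genes were lower (median -1.58), including Lrp2 (-1.96), the endocytic receptor megalin, and Acsm2 (-1.34). In the thick ascending limb 10 of 11 were lower (median -1.59), with the sodium-potassium-chloride cotransporter gene Slc12a1 (chromosome 2 of mm10, 125152510 to 125230002) at -3.92 ± 0.20, from an FPKM of 200 ± 6.38 to 12.5 ± 3.59, and the tight junction gene Cldn10 at -3.65. In the distal convoluted and connecting tubule 6 of 10 were lower (median -0.64), with the calcium-binding protein gene Calb1 at -3.07, and in the collecting duct 11 of 13 (median -0.77), with the bicarbonate exchanger gene Slc4a1 at -3.34. Of 20 genes of the TCA cycle and respiratory chain 17 were lower, including Idh2 (-1.29) and Ndufs1 (-1.08). Of 24 fatty acid oxidation genes 11 were lower and 5 higher, with Acadm at -1.45. Camera adjusted p with the preset correlation was 3.42e-11 for the proximal tubule, 0.000147 for the thick ascending limb, 0.00611 for the distal tubule, 0.000227 for the collecting duct, 1.55e-06 for the TCA cycle and 0.0285 for fatty acid oxidation. With an estimated correlation, adjusted p was 0.313 for the first 5 and 0.716 for fatty acid oxidation. The fatty acid oxidation call was lost with quantile normalization (adjusted p = 0.0881), without normoxic RIRI replicate 3 (0.0783) and without preconditioned RIRI replicate 2 (0.0578).

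Camera called none of the other 13 lists in this comparison (adjusted p from 0.0767 to 0.953). Of 16 monocyte and macrophage genes 8 were higher, including Cd68 (2.81), and 3 lower, including Csf1r (-1.37). Of 14 endothelial genes 8 were higher, including Nos3 (2.12), and 3 lower. Of 26 hypoxia and HIF targets 8 were higher, including Hk2 (2.27) and Adm (2.98), and 9 lower. Of 14 unfolded protein and integrated stress response genes 7 were higher, including Asns (3.62), and 4 lower. Counts of members higher and lower were 3 and 3 of 10 for podocytes, 5 and 2 of 11 for fibroblasts and pericytes, 1 and 1 of 3 for adipose tissue, 0 and 3 of 8 for red blood cells, 0 and 5 of 13 for the mitochondrial genome, 1 and 5 of 17 for the interferon response, 2 and 5 of 12 for heat shock, 4 and 0 of 6 for the cell cycle, and 4 and 7 of 15 for the circadian clock. Adjusted over the list alone, the counts of the 29 lists were the same except that 2 red blood cell, 3 interferon and 4 heat shock genes were lower. The median, mean and test differed in sign for adipose tissue, hypoxia and HIF targets, and heat shock.

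The comparison of preconditioned RIRI with normoxic RIRI asks how preconditioning changed the injured kidney. Of 5500 genes raised by the mean injury effect, 75.6% had a lower value in preconditioned mice and 36.7% were called as lower, and of 3697 genes lowered, 92.5% had a higher value and 61.7% were called as higher. Sprr2f changed by -3.69 ± 0.32, from an FPKM of 119 ± 18.3 to 9.53 ± 6.41 (SD, n = 3), Pdk4, an inhibitor of pyruvate dehydrogenase, by -3.27 ± 0.56, Angptl7, an angiopoietin-like protein, by -2.83 ± 0.38, Vgf, a neuropeptide precursor, by -2.71 ± 0.24, Fosl1 by -2.63 ± 0.24, and Dusp5, a phosphatase of ERK kinases, by -2.59 ± 0.34. Apoc3, an apolipoprotein of triglyceride-rich particles, was higher by 2.91 ± 0.26, Tmem52b by 2.85 ± 0.25, Keg1 by 2.76 ± 0.31, and Rhcg, an ammonia transporter of the collecting duct, by 2.68 ± 0.22, from an FPKM of 4.41 ± 1.93 to 32.1 ± 4.66. Sostdc1, a secreted antagonist of BMP and Wnt signals, was higher by 2.59 ± 0.40 and the lactate transporter gene Slc5a12 by 2.56 ± 0.26. BH-adjusted p (limma) was at most 9.73e-04 for these 12 genes. Lcn2 was lower (-1.65 ± 0.27, FPKM 730 ± 186) and Krt20 was lower (-2.43 ± 0.29), while Havcr1, another tubular injury gene and chosen here after its values were seen, had an FPKM of 365 ± 279 against 264 ± 187 in normoxic RIRI and was not called. In all, 3053 genes were higher and 2150 lower, of which 347 and 243 differed at least 2-fold, and the groups did not overlap in 5892 genes (47.7%, where chance gives 10%). The percent of calls that were higher was 58.7%, and it was 44.6% after median-ratio rescaling and 48.2% after quantile normalization, so which direction held more genes depended on the scaling. A fit of only the RIRI groups called 3373 genes, against 5203 in the fit of all groups.

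Of the 29 lists, camera called 8 as lower in preconditioned RIRI at the preset correlation and none at an estimated one. All 11 neutrophil genes were lower (median -1.65), including Mmp8 (-1.70), as were 20 of 24 tubular injury genes (median -1.02), including Plaur (-1.69), the urokinase receptor, and 13 of 22 IL-17 and NF-kB response genes (median -0.92), including Cebpb (-1.12) and Mmp9 (-1.07). Of 14 immediate early genes 7 were lower, with Klf6 at -1.63 and Atf3 at -1.33. Of 10 glucocorticoid targets 9 were lower, with Mt2 at -1.90, and of 15 NRF2 targets 7, with Srxn1 at -2.01. Of 13 cell death genes 4 were lower, with Mlkl at -1.42, and 1 higher, Pycard (0.76), an inflammasome adaptor. Of 14 endothelial genes 6 were lower, with Robo4 at -0.64, and 2 higher. Camera adjusted p with the preset correlation was 2.71e-06 for neutrophils, 1.33e-09 for tubular injury, 4.13e-05 for response genes and for immediate early genes, 7.1e-05 for glucocorticoid targets, 0.000631 for NRF2 targets, and 0.0394 for cell death genes and for endothelium. With an estimated correlation, adjusted p was 0.509 for response genes, 0.56 for endothelium and 0.461 for the other 6. The cell death call was lost without normoxic RIRI replicate 1 (0.0832) or 3 (0.0884), without preconditioned RIRI replicate 3 (0.0769), after median-ratio rescaling (0.0569), with a pseudocount of 0.1 (0.0533) and with a filter at FPKM 5 (0.293). The endothelium call was lost without normoxic RIRI replicate 3 (0.163), without preconditioned RIRI replicate 1 (0.067), with both rescalings (0.0524 and 0.0845) and with a filter at FPKM 5 (0.0621).

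The 5 lists called as higher, again at the preset correlation only, were of tubule segments and metabolism. In the thick ascending limb 8 of 11 genes were higher (median 0.90), with Cldn10 at 2.44, Slc12a1 at 2.31 ± 0.20 and an FPKM of 66.3 ± 20.2, and Bsnd, a chloride channel subunit, at 2.53. In the collecting duct 8 of 13 were higher (median 0.93), with Hsd11b2, which inactivates glucocorticoids, at 2.43 and the sodium channel subunit gene Scnn1g at 1.75. In the proximal tubule 11 of 24 were higher and 1 lower (median 0.23), with G6pc at 2.26 and Gatm at 2.55. Of 20 TCA cycle and respiratory chain genes 13 were higher, with Ndufs1 at 0.52, and of 24 fatty acid oxidation genes 11, with Etfb at 0.57. Camera adjusted p was 8.16e-05 for the thick ascending limb, 0.000196 for the collecting duct, 0.0015 for the TCA cycle, and 0.0394 for the proximal tubule and for fatty acid oxidation. With an estimated correlation, adjusted p was 0.461, 0.461, 0.509, 0.618 and 0.772 in that order. Without normoxic RIRI replicate 1, normoxic RIRI replicate 3 or preconditioned RIRI replicate 1, the call was lost for the proximal tubule (0.105, 0.163 and 0.0566) and for fatty acid oxidation (0.105, 0.239 and 0.0566), and for the latter also without preconditioned RIRI replicate 3 (0.225) and after median-ratio rescaling (0.0569).

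Camera called none of the other 16 lists between the RIRI groups (adjusted p from 0.0638 to 0.978). The interferon response, at 0.0638, was however called as higher in 9 of 20 alternatives, among them median-ratio rescaling (0.0215), quantile normalization (0.0351) and the replicate block (0.034). It rested largely on preconditioned RIRI replicate 1, without which its adjusted p was 0.626, against 0.0271 and 0.00267 without replicates 2 and 3. Among these, 2 of 19 IL-17 receptors and adaptors were higher, including the receptor subunit gene Il17rb (1.58 ± 0.24), and 5 lower, including the NF-kB subunit gene Rela (-0.68). Of 19 acute phase and STAT3 genes 4 were higher, including the complement gene C3 (2.23), and 6 lower, including Saa3 (-2.45). Of 17 interferon response genes 5 were higher, including Cmpk2 (1.14), of 16 monocyte and macrophage genes 3 were higher and 4 lower, with Chil3 at -1.93, and of 26 hypoxia and HIF targets 6 were higher and 6 lower. Adjusted over the list alone, the counts were 12 higher and 3 lower for the proximal tubule, 9 higher for the thick ascending limb, 4 higher and 7 lower for receptors and adaptors, 14 lower for response genes, 7 lower for acute phase, 1 lower for fatty acid oxidation and 8 lower for immediate early genes, with no change in the others. The median, mean and test differed in sign for hypoxia and HIF targets, the unfolded protein response, the cell cycle and the circadian clock.

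For the injury genes as a whole, 9197 genes were called for the mean injury effect, 5500 raised and 3697 lowered. In 82.42% of them the difference between preconditioned RIRI and normoxic RIRI ran against the injury, whether it was called or not. Of the 9 other splits of the RIRI libraries, 1 gave a larger share (83.57%), where each split was given the larger of its shares against and along the injury. The injury score, from 912 genes raised and 801 lowered at least 2-fold, was -1.87 ± 0.067 (SD, n = 3) in normoxic sham, -1.86 ± 0.028 in preconditioned sham, 2.01 ± 0.106 in normoxic RIRI and 0.597 ± 0.322 in preconditioned RIRI. On a scale from 0% in normoxic sham to 100% in normoxic RIRI, preconditioned RIRI stood at 63.6% ± 8.3 and preconditioned sham at 0.2%. All 3 preconditioned RIRI scores lay below all 3 normoxic RIRI scores (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 allows).

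**Figure D1:**
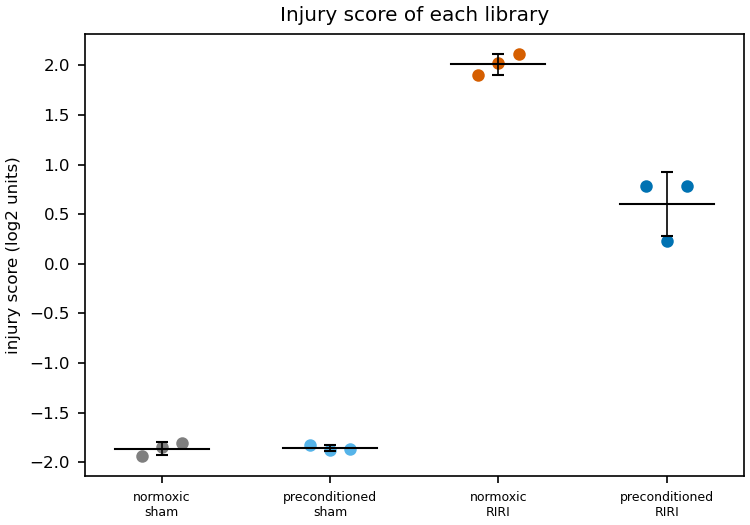
Injury score (log2 units) of each library, with the group mean as a line and the SD of 3 mice as bars. The preconditioned RIRI mean of 0.597 lies between the sham means (-1.87 and -1.86) and the normoxic RIRI mean of 2.01.

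**Figure D2:**
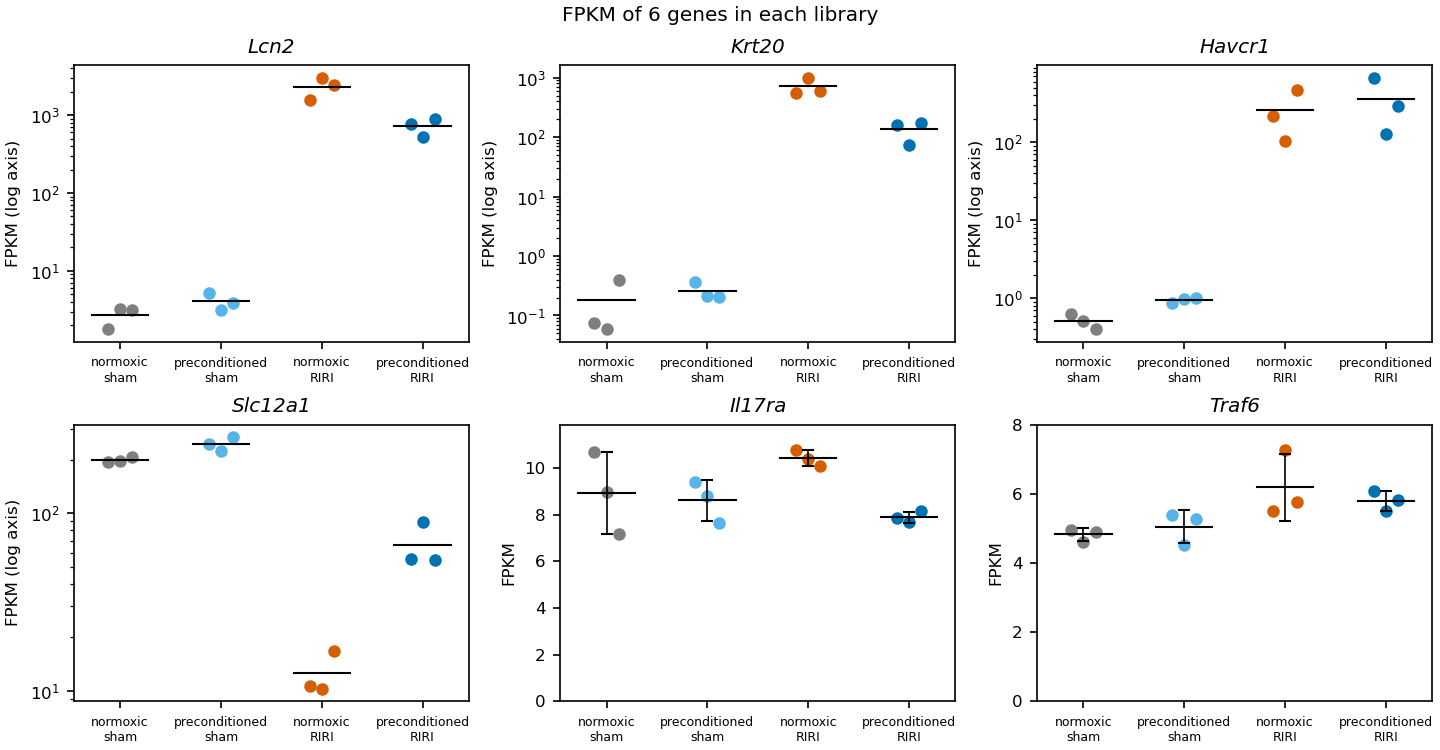
FPKM of 6 genes in each library, on a log axis for Lcn2, Krt20, Havcr1 and Slc12a1, with group means as lines and, on the linear axes of Il17ra and Traf6, the SD of 3 mice as bars. Lcn2 averaged 2328 in normoxic and 730 in preconditioned RIRI, while Havcr1 averaged 264 and 365.

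The comparison of preconditioned sham with normoxic sham asks what preconditioning did without injury. The largest decrease was of Cyp4a12a, which encodes an omega-hydroxylase of arachidonic acid, at -2.75 ± 0.14 (adjusted p = 2.28e-06, limma), from an FPKM of 84.5 ± 10.3 to 11.7 ± 1.41 (SD, n = 3). The protease inhibitor gene Pzp changed by -2.21 ± 0.20, Acsm3, a medium-chain acyl-CoA synthetase, by -1.85 ± 0.15, Srd5a2, which converts testosterone to dihydrotestosterone, by -1.69 ± 0.21, the lipase family gene Lipo3 by -1.55 ± 0.19, and the chemokine gene Ccl28 by -1.53 ± 0.19, with adjusted p of at most 0.0034. The increases were of Cyp4a14, a fatty acid omega-hydroxylase, by 4.02 ± 0.75 (adjusted p = 0.0474), the amino acid transporter gene Slc7a12 by 2.22 ± 0.26 (0.0034), Rdh16f2, a retinol dehydrogenase family member, by 1.69 ± 0.23 (0.00766), the glutathione transferase gene Gsta2 by 1.18 ± 0.22 (0.0474), the glutamine transporter gene Slc38a3 by 1.15 ± 0.20 (0.0382), and the apolipoprotein gene Apoe by 0.90 ± 0.17 (0.0485). The calls of Cyp4a14, Gsta2, Slc38a3 and Apoe were each lost without any 1 of the 6 sham libraries, with adjusted p of up to 0.215, 0.171, 0.21 and 0.229, and after quantile normalization (0.0632, 0.0625, 0.0558 and 0.0825), while their log2 fold changes stayed positive. Srd5a2 was not called with a pseudocount of 0.1 (0.0543). Cyp4a12a lies on chromosome 4 of mm10 from 115299046 to 115332815.

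Of 12357 genes, 23 were higher and 29 lower at adjusted p under 0.05 (limma), while 1726 had an unadjusted p under 0.05. The sham groups did not overlap in 3627 genes (29.4%, where chance gives 10%). Leaving out 1 library at a time gave 6 to 38 higher and 15 to 42 lower genes. The number higher was 11, 6 and 8 without normoxic sham replicates 1, 2 and 3, 10 and 11 without preconditioned sham replicates 1 and 3, 37 without normoxic RIRI replicate 2 and 38 without preconditioned RIRI replicate 2, and the number lower was 16, 17 and 15 without normoxic sham replicates 1, 2 and 3 and 19 without preconditioned sham replicate 3. The percent of calls that were higher was 44.2%, against 21.5% after median-ratio rescaling, 23.3% after quantile normalization and 32.3% with a pseudocount of 0.1. A fit of only the sham groups gave 192 higher and 111 lower genes (63.4% higher), so which direction held more genes depended on the fit.

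In the sham kidneys 10 lists were called at the preset correlation, although few of their members were, and none at an estimated one. Heat shock genes had a median of -0.73, with the chaperone gene Hsp90aa1 called (-0.95 ± 0.18, adjusted p = 0.0474, limma) and 6 of 12 lower adjusted over the list alone. Unfolded protein and integrated stress response genes had a median of -0.46, with 8 of 14 lower adjusted over the list alone. Proximal tubule genes had a median of -0.10, with Acsm2 called (-0.44 ± 0.07) and 5 of 24 lower adjusted over the list alone. Without Kap and 3 other male-biased members, left out after the data were seen, the other 20 had a median of -0.01 and were still called with the preset correlation (adjusted p = 0.000774) but not with an estimated one (0.546). Interferon response genes had a median of 0.87, with 13 of 17 higher adjusted over the list alone, red blood cell genes a median of 1.08, with 5 of 8 higher in that count, and collecting duct genes a median of 0.34, with 7 of 13 higher. Camera adjusted p with the preset correlation was 3.3e-13 for heat shock, 4.11e-12 for the unfolded protein response, 3.97e-07 for the proximal tubule and for the interferon response, 0.00559 for red blood cells and 2.98e-05 for the collecting duct. With an estimated correlation, adjusted p was 0.198, 0.198, 0.266, 0.546, 0.546 and 0.302 in the order heat shock, unfolded protein response, proximal tubule, interferon, red blood cells and collecting duct. The calls of Hsp90aa1 and Acsm2 were lost without any 1 of the 6 sham libraries, with adjusted p of up to 0.215 and 0.129, and after quantile normalization (0.0558 and 0.0758). Without normoxic sham replicate 3, which had the highest Hspa1a (FPKM 31.9, a gene chosen after its values were seen), the heat shock median was -0.35.

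The other 4 lists called as lower in preconditioned sham had small medians, at -0.12 for the mitochondrial genome, -0.10 for the circadian clock, -0.002 for NRF2 targets and -0.02 for IL-17 and NF-kB response genes. Camera tests a list against the other genes, and the median over all genes was 0.0642 here. Lower therefore means lower in relation to the other genes. Camera adjusted p was 0.00466, 0.00466, 0.0267 and 0.0406 in that order with the preset correlation, and adjusted p was 0.498, 0.254, 0.546 and 0.844 with an estimated correlation. The mitochondrial genome call was lost with quantile normalization (0.478) and without preconditioned sham replicate 2 (0.0972), and the circadian call after median-ratio rescaling (0.073). The NRF2 call was lost after both rescalings (0.073 and 0.486), without normoxic RIRI replicate 2 (0.0763) and without preconditioned sham replicate 3 (0.227). The response gene call was lost after both rescalings (0.662 and 0.486), without normoxic sham replicates 2 (0.0593) or 3 (0.463), and without preconditioned sham replicates 1 (0.0501) or 3 (0.227). Adjusted over the list alone, 1 NRF2 target was higher and 2 were lower, and 2 fatty acid oxidation genes, 2 cell death genes, 1 podocyte gene and 1 acute phase gene were higher, with 1 tubular injury gene higher and 1 lower. Camera called none of the other 19 lists (adjusted p from 0.14 to 0.975), neutrophils (0.17) and tubular injury (0.52) among them. Some of these were called in 1 or 2 of 20 alternatives. Without normoxic sham replicate 1, neutrophils (0.0374), immediate early genes (0.011) and p53 targets (0.0179) were called as lower, and immediate early genes also without preconditioned sham replicate 2 (0.000159). Without a filter, cell cycle genes, of which 6 of 20 passed the filter, were called as lower (6.67e-10) and podocytes as higher (0.0435), and podocytes also without normoxic sham replicate 2 (0.00605). The thick ascending limb was called as higher after quantile normalization (0.0357) and with only the sham groups fitted (0.012), and the TCA cycle after quantile normalization (0.016). The median, mean and test differed in sign for neutrophils, monocytes and macrophages, the distal tubule, fibroblasts, tubular injury, acute phase, hypoxia and HIF targets, fatty acid oxidation, the cell cycle and p53 targets.

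The comparison of preconditioned RIRI with preconditioned sham asks what the injury did in preconditioned mice. The genes with the largest changes were again those of damaged tubules, with Havcr1 at 7.23 ± 0.55, Lcn2 at 7.15 ± 0.27, Krt20 at 6.68 ± 0.29 and Plin2 at 5.01 ± 0.51. Fgg, the gamma chain of fibrinogen, rose by 4.78 ± 1.14 (adjusted p = 0.0041, limma), with 340, 9.85 and 43.4 FPKM in the 3 mice and no call with voom (0.1), and the glutathione transferase gene Gsta1 by 4.72 ± 0.37. The largest decreases were of the epidermal growth factor gene Egf at -3.08 ± 0.32, Nccrp1 at -3.02 ± 0.22, the lectin family gene Clec2h at -2.75 ± 0.29, the parvalbumin gene Pvalb at -2.65 ± 0.21, Gatm at -2.65 ± 0.31 and Hsd3b2 at -2.60 ± 0.42. Fgg apart, adjusted p was at most 3.45e-04 for these 12 genes. In all 4083 genes were higher and 2397 lower, of which 581 and 465 changed at least 2-fold, and the groups did not overlap in 7824 genes (63.3%, where chance gives 10%). The percent of calls that were higher was 63%, against 52.3% after median-ratio rescaling and 51.1% after quantile normalization.

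Of the 29 lists, camera called 10 as higher and 6 as lower with injury in preconditioned mice at the preset correlation, and none at an estimated one. Higher were 23 of 24 tubular injury genes (median 2.96), with Spp1 at 3.71, 18 of 22 IL-17 and NF-kB response genes (1.61), with the adhesion molecule gene Icam1 at 1.45, 13 of 19 acute phase and STAT3 genes (1.63), with C3 at 3.62, and 13 of 14 unfolded protein and integrated stress response genes (1.18), with Asns at 2.95. Higher too were 7 of 11 neutrophil genes (0.63), with S100a8 at 3.35, 12 of 15 NRF2 targets (0.92), 8 of 11 p53 targets (0.66), 9 of 19 IL-17 receptors and adaptors (0.28), 7 of 13 cell death genes (0.43) and 7 of 14 immediate early genes (0.69). Lower were 23 of 24 proximal tubule genes (-1.02), with the phosphate transporter gene Slc34a1 at -1.47, 6 of 11 thick ascending limb genes (-0.93), with Slc12a1 at -1.92, 9 of 10 distal tubule genes (-0.56), 8 of 13 collecting duct genes (-0.42), 16 of 20 TCA cycle and respiratory chain genes (-0.46) and 3 of 17 interferon response genes (-0.55), with Rsad2 at -1.12. Camera adjusted p with the preset correlation ran from 6.03e-14 for the proximal tubule and 1.09e-12 for tubular injury to 0.0292 for cell death genes and 0.0459 for immediate early genes. With an estimated correlation none of these lists was called, and adjusted p was 0.186 for the proximal tubule, 0.2 for tubular injury, 0.606 for neutrophils and immediate early genes, 0.4 for response genes, 0.487 for acute phase, 0.617 for interferon and 0.243 to 0.32 for the other 9. The cell death call was lost without preconditioned RIRI replicate 2 (0.0533), and the interferon call without preconditioned sham replicate 3 (0.0522) or preconditioned RIRI replicates 2 (0.0545) or 3 (0.092). The immediate early call was lost without normoxic RIRI replicates 2 (0.0694) or 3 (0.0565), preconditioned sham replicates 1 (0.059) or 3 (0.155), or preconditioned RIRI replicates 1 (0.0636) or 3 (0.0523).

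Camera called none of the other 13 lists in preconditioned mice (adjusted p from 0.0631 to 0.753). Heat shock genes, with 6 of 12 higher, had an adjusted p of 0.0893, cell cycle genes, with 5 of 6 higher, 0.0683, and fatty acid oxidation genes, with 3 higher and 7 lower of 24, 0.0878. Adjusted over the list alone, 21 response genes, 14 acute phase genes, 1 adipose gene and 4 circadian genes were higher, and 17 TCA cycle, 2 interferon, 2 adipose, 0 red blood cell and 0 mitochondrial genome genes were lower, with no change in the other lists. The median, mean and test differed in sign for podocytes, endothelium, hypoxia and HIF targets, fatty acid oxidation and the circadian clock.

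**Figure D3:**
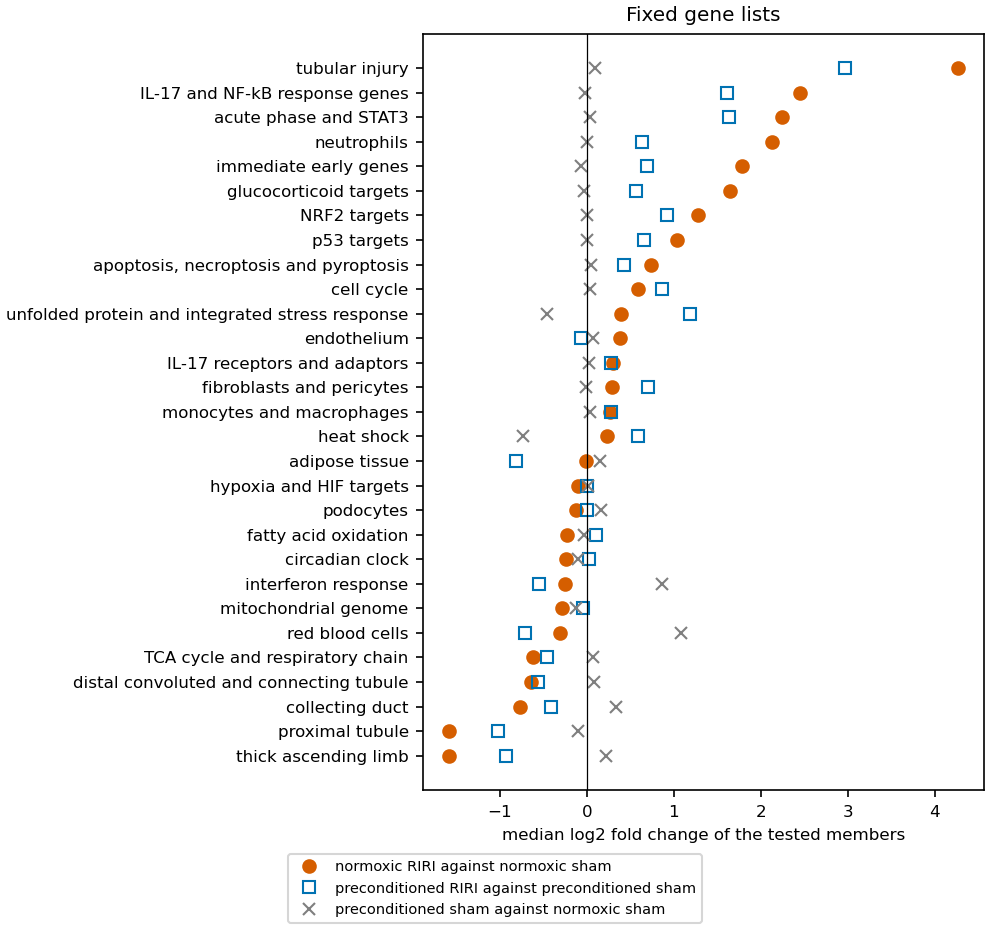
Median log2 fold change of the tested members of each of the 29 fixed lists, for the injury in normoxic mice (circles), the injury in preconditioned mice (squares) and preconditioning without injury (crosses). Tubular injury genes had a median of 4.27 in normoxic and 2.96 in preconditioned mice, and proximal tubule genes -1.58 and -1.02.

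The interaction asks whether the injury effect itself differed with preconditioning. The injury effect was more positive in preconditioned mice for 1393 genes and more negative for 1560 (limma), of which 325 and 253 differed at least 2-fold. Genes that injured normoxic kidneys lost and preconditioned ones lost less included Keg1 (3.35 ± 0.44), Glyctk, a glycerate kinase (2.72 ± 0.44), Tmem52b (2.66 ± 0.35) and Hykk (2.53 ± 0.24). Keg1 fell from an FPKM of 1619 ± 241 to 121 ± 68.0 in normoxic mice and from 1072 ± 85.4 to 762 ± 195 in preconditioned mice. Ccl28 (2.86 ± 0.27) had mean FPKM of 7.34 and 0.602 in normoxic sham and RIRI and 1.94 and 3.07 in preconditioned sham and RIRI, and Sdf2l1, an endoplasmic reticulum chaperone component (2.60 ± 0.44), had 24.7 and 10.04 against 11.8 and 29.7. More negative were Sprr2f (-3.77 ± 0.46), Pdk4 (-2.97 ± 0.79), Rasd1, a Ras-related GTPase (-2.75 ± 0.73), Vgf (-2.71 ± 0.35), Fosl1 (-2.62 ± 0.34) and Akap12, a kinase anchoring protein (-2.57 ± 0.41). Adjusted p was 0.0202 for Pdk4, 0.0199 for Rasd1 and at most 0.00242 for the other 10. Without normoxic sham replicate 1 Rasd1 was at adjusted p = 0.0511, and without a filter Pdk4 was at 0.0648 and Rasd1 at 0.0643. With voom on recovered reads, chosen after the data were seen, Sprr2f was at 0.0598, Vgf at 0.297 and Fosl1 at 0.38, and of the list members named for the interaction Krt20 was at 0.171 and Mmp8 at 0.305.

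Across genes, the injury effects in normoxic and preconditioned mice correlated with a Pearson r of 0.892 and a Spearman rho of 0.87 over 12357 genes, which are not independent replicates. They were called with the same sign in 5839 genes and with opposite signs in 46. Of the 912 genes raised at least 2-fold by the mean injury effect, 845 (92.7%) rose less in preconditioned mice, with medians of 1.71 against 1.09, and of the 801 lowered, 739 (92.3%) fell less, with medians of -1.70 against -1.06.

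Of the lists, 7 were called with a more negative injury effect in preconditioned mice at the preset correlation, and none at an estimated one. They were tubular injury (17 of 24 genes more negative, median -1.03, with Krt20 at -2.53), neutrophils (7 of 11, -1.25, Mmp8 at -1.67), IL-17 and NF-kB response genes (4 of 22, -0.78, Lcn2 at -2.11), immediate early genes (5 of 14, -1.09, Klf6 at -1.78), glucocorticoid targets (5 of 10, -1.17, Mt1 at -2.21), NRF2 targets (5 of 15, -0.36, Srxn1 at -2.07) and endothelium (6 of 14, -0.35, Robo4 at -0.84). A more positive effect was found in the proximal tubule (12 of 24, 0.42, G6pc at 2.48), the thick ascending limb (6 of 11, 0.80, Slc12a1 at 2.01), the collecting duct (6 of 13, 0.25, Hsd11b2 at 2.09), fatty acid oxidation (6 of 24, 0.21, Etfb at 0.59) and the TCA cycle and respiratory chain (3 of 20, 0.21, Ndufs1 at 0.49). Camera adjusted p with the preset correlation was 1.09e-07 for tubular injury, 2.28e-05 for the proximal tubule, 0.000144 for neutrophils, 0.000992 for the thick ascending limb and between 0.00205 and 0.0258 for the others, while adjusted p was 0.613 for all 12 with an estimated correlation. Calls were lost without normoxic RIRI replicate 1 for the collecting duct (0.0794), NRF2 targets (0.0599) and fatty acid oxidation (0.0599), without normoxic RIRI replicate 3 for the TCA cycle (0.0565), endothelium (0.0874) and fatty acid oxidation (0.0874), without preconditioned RIRI replicate 3 for fatty acid oxidation (0.135), and with a filter at FPKM 5 for neutrophils (0.0921) and NRF2 targets (0.0801). Adjusted over the list alone, 18 tubular injury, 9 neutrophil, 7 response, 6 immediate early, 6 NRF2 and 8 endothelial genes were more negative, 7 fatty acid oxidation, 2 TCA cycle, 6 heat shock and 1 endothelial genes more positive, with 4 unfolded protein response genes more negative and 0 receptors and adaptors more positive. The other 17 lists were not called (adjusted p from 0.0526 to 0.985). The lowest was that of cell death genes (0.0526), which was called as more negative in 11 of 19 alternatives, among them median-ratio rescaling (0.0432), quantile normalization (0.04) and the replicate block (0.0446). Also not called were the unfolded protein response (0.19), of which 6 of 14 genes were more positive and 2 more negative, and heat shock (0.0624), with 3 of 12 more positive. The interferon response (0.664) was called as more negative without preconditioned RIRI replicate 1 (0.0186), so its result depended on that library. The median, mean and test differed in sign for red blood cells, fibroblasts, and hypoxia and HIF targets.

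The title of the study names the IL-17A/IL-17RA/TRAF6 axis. Il17ra, the shared IL-17 receptor subunit, on chromosome 6 of mm10 from 120463181 to 120483731, had an FPKM of 8.94 ± 1.76 (SD, n = 3) in normoxic sham, 10.4 ± 0.354 in normoxic RIRI, 8.62 ± 0.891 in preconditioned sham and 7.89 ± 0.234 in preconditioned RIRI. All 3 Il17ra values of preconditioned RIRI lay below all 3 of normoxic RIRI. Between these groups 47.7% of all tested genes did not overlap and 42.1% were called. The log2 fold change of Il17ra was 0.22 ± 0.11 with injury in normoxic mice (adjusted p = 0.11, limma) and -0.36 ± 0.11 in preconditioned against normoxic RIRI (adjusted p = 0.025). That call was lost without a filter (0.0553), without normoxic RIRI replicates 1 (0.0579) or 2 (0.0532) and without preconditioned RIRI replicates 1 (0.0546) or 2 (0.0706), and the injury effect in normoxic mice was called without normoxic sham replicate 1 (0.0143). It was -0.04 (0.927) between the sham groups, -0.11 (0.445) with injury in preconditioned mice and -0.32 (0.165) in the interaction. Traf6, an adaptor ubiquitin ligase, on chromosome 2 from 101678420 to 101701668, had 4.83 ± 0.186, 6.18 ± 0.956, 5.05 ± 0.464 and 5.80 ± 0.290 in the same order of groups. It rose by 0.29 ± 0.10 with injury in normoxic mice (adjusted p = 0.0157), a call lost after median-ratio rescaling (0.0851), after quantile normalization (0.25), without normoxic sham replicate 2 (0.0534) and without normoxic RIRI replicate 2 (0.0574). It was not called between the RIRI groups (-0.07, adjusted p = 0.575), between the sham groups (0.05, 0.858), with injury in preconditioned mice (0.17, 0.157) or in the interaction (-0.12, 0.538). Il17a has no row in the table and was not analysed here.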

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

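The tests by other splits of the libraries and the scaling test of the injury genes were chosen after the results were seen. The results below stood out because the injury effect differed between preconditioned and normoxic mice by the interaction test of limma or, for lists, of camera with the preset correlation. None of the 12 lists was called with an estimated correlation (adjusted p = 0.613 for each). The injury effect was more positive in preconditioned mice for 1393 genes and more negative for 1560. The log2 difference was 3.35 for Keg1, 2.86 for Ccl28, 2.72 for Glyctk, 2.66 for Tmem52b, 2.60 for Sdf2l1, 2.53 for Hykk, -3.77 for Sprr2f, -2.97 for Pdk4, -2.75 for Rasd1, -2.71 for Vgf, -2.62 for Fosl1 and -2.57 for Akap12. The median over the list was -1.25 for neutrophils, 0.42 for the proximal tubule, 0.80 for the thick ascending limb, 0.25 for the collecting duct, -0.35 for endothelium, -0.78 for IL-17 and NF-kB response genes, -1.03 for tubular injury, 0.21 for fatty acid oxidation, 0.21 for the TCA cycle and respiratory chain, -0.36 for NRF2 targets, -1.09 for immediate early genes and -1.17 for glucocorticoid targets.

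Of 100 splits within the sham and RIRI groups, 2, with the real one, gave as many interaction genes as the real 2953 (highest other 3506). The splits regroup the preconditioning labels, so they ask whether preconditioning had any effect. They cannot decide whether the injury effect differed in more genes than chance gives, and splits that mix the real groups also widen the spread. The split with 3506 exchanged the labels of the RIRI groups alone and so kept both real groupings. Its contrast is, in size, the sum of the preconditioning effects in RIRI and in sham kidneys. The next, with 2557, 2443 and 2421 genes, kept the real RIRI groups and regrouped the sham libraries, which points to the difference between the RIRI groups as the larger part of the count. For the interaction lists 41 of the 100 splits gave as many (12, highest other 18), so chance cannot be excluded for the number of lists.

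The comparisons of 3 against 3 libraries have 10 splits, which is too few for a share under 0.05. For genes, 1 of 10 splits, the real one, gave as many as the real count in each comparison. The real count and the highest other were 8859 and 0 for normoxic RIRI against normoxic sham, 5203 and 4 for preconditioned RIRI against normoxic RIRI, 52 and 1 for preconditioned sham against normoxic sham, and 6480 and 26 for preconditioned RIRI against preconditioned sham. For lists, in the same order, 2, 3, 2 and 3 of 10 splits gave as many, with 16 and 17, 13 and 17, 10 and 14, and 16 and 19 as the real number and the highest other. For the share of injury genes that moved, each split was given the larger of its shares against and along the injury. By this measure 2 of 10 splits, with the real one, gave as much. The real split had 82.42%, and the split of normoxic RIRI 1 and 3 with preconditioned RIRI 3 against the rest had 83.57%.

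The pattern behind these results, injury genes closer to sham in preconditioned RIRI kidneys, was weighed against 2 technical explanations. The FPKM scaling is argued against, since the share stood at 84.89% under quantile normalization, where a scaling effect was set to fall under 60%. A larger part of uninjured tissue in the preconditioned RIRI samples stays open. A mixture of injured and sham kidney puts every gene between the pure states, and after median-ratio rescaling 193 of 5290 genes called between the RIRI groups (3.6%) lay beyond both normoxic RIRI and preconditioned sham, where at most 5% was set beforehand. As deposited 251 genes (4.8%) lay beyond both, and 250 (4.9%) after quantile normalization, with 11 to 14 genes at least 2-fold beyond both. Of these genes 218 were higher as deposited, 110 after median-ratio rescaling and 140 after quantile normalization, so the balance of directions depended on the scaling. A mixture alone does not give values such as those of C3 and Slc13a1, genes chosen after their values were seen. They stood at 68.5 and 486 FPKM in preconditioned RIRI, 13.2 and 136 in normoxic RIRI, and 4.31 and 182 in preconditioned sham. The other genes beyond both passed the adjusted p cutoff with no minimum distance, so some can be false calls. For the genes not beyond both, the data go with a smaller injured part of the kidney, with milder injury in each cell, or with both. Bulk tissue does not separate these.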

How the results depend on the processing

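The voom alternative and the proximal tubule list without male-biased members were added after the data had been seen; all others were planned. The gene counts stayed within 1.5 times their value under the pseudocount, both filters, both rescalings, no trend, the block and voom, except in the sham comparison, where the genes higher (23) came to 10 with a pseudocount of 0.1, 14 after median-ratio rescaling and 10 after quantile normalization, and the genes lower (29) to 51 after median-ratio rescaling; the cause was not tested. With the replicate number as a block the higher count was 12. Equal numbers did not pair the libraries, since same-number libraries correlated at a median r of 0.008 and others at -0.015, and 6 of 12 libraries correlated more with their own number. Fitting only the groups compared gave 192 higher and 111 lower between the sham groups and 2002 and 1371 between the RIRI groups. The groups spread unequally, with a chi-square per gene between libraries of a group of 12.06 to 27.64 in sham and 33.05 to 74.12 in RIRI. The main fit shares an estimate of the spread, so it can call too many genes between the RIRI groups and too few between the sham groups. A minimum log2 fold change of 1, which removes small changes by construction, left 1379 higher and 1196 lower for normoxic RIRI against sham, 347 and 243 between the RIRI groups, 8 and 13 between the sham groups, 581 and 465 for preconditioned RIRI against sham, and 325 and 253 in the interaction. The share of injury genes moved back was 87.15% after median-ratio rescaling and 84.89% after quantile normalization, against 82.42%. With an estimated inter-gene correlation 0 lists were called by camera in each of the 5 comparisons, the interaction included, against 16, 13, 10, 16 and 12; the estimated correlations, 0.022 to 0.863, all exceeded the preset 0.01.

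Leaving out 1 library at a time gave 6 to 38 higher and 15 to 42 lower between the sham groups and a share of 80.44% to 85.15%. The other counts stayed within 1.5 times, with 2260 to 3316 higher and 1580 to 2160 lower between the RIRI groups and 978 to 1793 and 1077 to 1776 in the interaction. The sign reversed in genes that were not called, for Traf6 between the sham groups (-0.022 after median-ratio rescaling, -0.04 after quantile normalization) and between the RIRI groups (-0.139 to 0.035 over the libraries left out), and for Il17ra between the sham groups (-0.172 to 0.087). Over the alternatives, the named genes that were called kept their call in 2444 of 2484 cases for normoxic RIRI against sham, 2194 of 2233 between the RIRI groups, 216 of 294 between the sham groups, 2285 of 2321 for preconditioned RIRI against sham and 1615 of 1747 in the interaction, and 0 reversed. Most of these genes were picked for a large change or a small adjusted p, so the cases do not measure how stable calls are at large. Of all 5203 genes called between the RIRI groups, a fit of only these groups kept 3342. A filter at FPKM 5, which leaves fewer genes, ended the camera call of cell death genes in normoxic mice (adjusted p = 0.152), in preconditioned mice (0.23) and between the RIRI groups (0.293). It also ended those of p53 (0.0508) and glucocorticoid targets (0.0536) in normoxic mice, of the proximal tubule (0.0578), fatty acid oxidation (0.0578) and endothelium (0.0621) between the RIRI groups, of the circadian clock (0.0814) and response genes (0.1) between the sham groups, of immediate early genes (0.135) in preconditioned mice, and of neutrophils (0.0921) and NRF2 targets (0.0801) in the interaction. A pseudocount of 0.1 ended the calls of the proximal tubule and fatty acid oxidation between the RIRI groups (0.0509 each), and a fit of only the groups compared ended these (0.0567 and 0.0555), fatty acid oxidation in normoxic mice (0.079) and NRF2 targets between the sham groups (0.0905). No filter ended the sham calls of response genes (0.0884), NRF2 targets (0.0878) and the mitochondrial genome (0.0827), and the block ended response genes there (0.0502) and immediate early genes in preconditioned mice (0.0512). Lists not called were called in some alternatives, most often cell death genes in the interaction (11 of 19), the interferon response between the RIRI groups (9 of 20), heat shock (6 of 20) and the cell cycle (5 of 20) in preconditioned mice, and heat shock in the interaction (4 of 19). Fewer alternatives called p53 targets (3 of 20, lowest adjusted p = 0.0376), acute phase genes (2, 0.0285) and monocytes and macrophages (1, 0.0266) as lower and red blood cells (2, 0.0029) as higher between the RIRI groups. In preconditioned mice, 1 each called red blood cells (0.00812) and fatty acid oxidation (0.0164) as lower and monocytes and macrophages (0.0373) as higher, and in normoxic mice 1 called the mitochondrial genome (0.0402) as lower. Without a filter, cell cycle genes were also called in the interaction (0.00195), as more positive. The lists of T and NK cells, B and plasma cells and the adrenal gland could be tested only without a filter, where T and NK cells were called as lower in normoxic RIRI against sham (0.0215) and the other 14 results were not called (0.0674 to 0.858). Read depth, at 33035307 to 35632033 recovered reads per library, limits genes of low level such as Il17f, Il17c and Il25, whose highest FPKM were 0.139, 0.0801 and 0.0279 and which were not tested and are named outside the rule.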

Other observations

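Some genes of preconditioned RIRI kidneys lay beyond both normoxic RIRI and preconditioned sham kidneys. They were chosen after their values were seen, and normoxic sham did not enter the choice. The complement gene C3 was higher by 2.23 than in normoxic RIRI and by 3.62 than in preconditioned sham, with a mean FPKM of 68.5 ± 28.2 (SD, n = 3) against 13.2 ± 3.91 and 4.31 ± 0.670. Serpina10, an inhibitor of coagulation factors, was higher by 2.00 and 4.09, and Slc13a1, the sodium-sulfate cotransporter of the proximal tubule, by 1.84 and 1.41, at 486 ± 42.7 FPKM against 136 ± 22.6 and 182 ± 8.23. The endoplasmic reticulum chaperone genes Sdf2l1, Pdia4 and Hyou1, the collagen gene Col1a1 and the IL-17 receptor subunit gene Il17rb were also above both groups. The unfolded protein list, which holds these chaperone genes, had a median log2 fold change of -0.461 in preconditioned against normoxic sham. Whether the chaperone genes exceeded normoxic sham was not tested. The glutamine synthetase gene Glul was below both (-0.91 and -1.40), as was Cyp2e1 (-0.68 and -1.09). After median-ratio rescaling, 4 of 24 proximal tubule genes were below both, Slc22a7, Slc22a30, Cyp2e1 and Cyp4b1, and 0 above.

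Preconditioned RIRI kidneys differed among themselves, as shown by genes chosen after their values were seen. Il6 had an FPKM of 8.25 in replicate 1 against 0.471 and 1.14 in replicates 2 and 3, and S100a8 had 34.4 against 7.14 and 13.5, while normoxic RIRI had 6.55 to 12.3 for Il6 and 34.1 to 81.7 for S100a8. The interferon gene Irf7 stood at 37.9 in that replicate and at 6.84 and 6.15 in the others, with 21.9 to 52.7 in preconditioned sham and 7.44 to 9.81 in normoxic sham. The red blood cell gene Alas2 ran the other way, with 4.36 in replicate 1, 25.4 and 12.1 in replicates 2 and 3, and a mean of 19.8 ± 0.827 in preconditioned sham against 7.98 ± 0.760 in normoxic sham.

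The lower heat shock genes of preconditioned sham kidneys were weighed with tests written beforehand. Camera called the list at the preset correlation only (adjusted p = 0.198 with an estimated one), and 1 of its 12 genes was called. The FPKM scaling is argued against, since the median of the list was -0.765 or lower under both rescalings. That the pattern comes from 1 normoxic sham library with high heat shock genes cannot be told apart from a group difference. Without normoxic sham replicate 3 the median was -0.348, between the bounds of -0.25 and -0.4 set for the test, with Hspa1a at 12.9, 4.51 and 31.9 FPKM in normoxic sham and 5.82, 6.02 and 7.49 in preconditioned sham. Hsp90aa1, and Hspa5 of the unfolded protein list, were higher in all 3 normoxic sham libraries than in all 3 preconditioned ones. The sham groups did not overlap in 29.4% of all tested genes, so these picked genes do not settle the question.

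Genes known to be higher in male than in female mouse kidney, such as Cyp4a12a, Acsm3 and Kap, were seen to be lower in preconditioned sham, and Kap and the genes below are named outside the rule for named genes. Ddx3y was present at 4.94 to 11.1 FPKM and Xist at no more than 0.0066 FPKM in the 12 libraries. A list of 12 other male-biased genes was then drawn up, with its prediction. Slc22a30, Slc7a13 and Cyp2e1 also stand in the proximal tubule list, whose result in the sham groups was known. The other 9 stand outside that list, but they were measured in the same sham libraries, and their separate test was chosen after the result was seen. These 9 had a median log2 fold change of -0.58, lower than in all 10000 random lists matched on expression (5th percentile -0.03), and 8 of 9 were lower. For all 12 the median was -0.57, also lower than in all 10000 (5th percentile -0.02), and 11 of 12 were lower, although 0 of 12 passed an adjusted p under 0.05 (limma). Slco1a1 had -2.12, Odc1 -0.89 and Cyp4a12b 0.23. The median was -0.585 to -0.476 when 1 sham library was left out, and at most 0.283 in size in the other 9 splits of the sham libraries. These splits are too few for a share under 0.05. The random lists were matched on expression only and took no account of genes that vary together, so they do not measure chance between 3 and 3 mice. No test that allows for such correlation was run on this list. A loss of all proximal tubule cells alike is argued against as the source. The 20 proximal tubule markers other than Slc22a30, Slc7a13, Cyp2e1 and Kap had a median of -0.011, a difference of -0.559, and the 9 differed from the whole proximal tubule list by -0.48. Camera still called these 20 as lower with the preset correlation (adjusted p = 0.000774), but not with an estimated one (0.546). The markers were not divided by segment, so a loss confined to a part of the proximal tubule was not tested. Between the RIRI groups the median of the 12 was -0.229, with 1 called as lower. With injury in normoxic mice it was -1.37, with 9 called as lower, so these genes also fell without preconditioning. Weaker androgen-dependent expression after hypoxic preconditioning is a candidate explanation, held as a hypothesis, since hormone levels were not measured in the data used here and the list was tested on the libraries that prompted it.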
